A study of Homo sapiens with 9 samples.

How the data were processed

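Total RNA of 9 HepG2 cultures was profiled on Affymetrix arrays, with 3 arrays each for the non-target control, line 18.5 and line 19.5. Per the labels' protocols, cells were transduced with lentiviral hairpins (multiplicity of infection of 5 for the knock-down lines), selected in 2 µg/ml puromycin, expanded as mass cultures, grown for 48 h and extracted with Trizol, and 100 ng of RNA was labelled with biotin by a whole-transcript kit. The labels call the replicates biological and do not say how far their cultures were kept apart, so p-values measure the spread between these samples. Groups and replicate numbers were taken from the sample titles.

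The authors deposited 1 table of intensity values per probe, made with RMA per the submitters' processing notes. That method combines background correction, quantile normalization and a summary over the probes of a set. Its version and the program are not given in the sources used here. RMA usually gives log2 values, and the deposited intensity values were on a linear scale, so log2 was taken before any test. The design had foreseen log2 values with this step for a linear table. Quantile normalization removes differences in overall level between arrays, yet the deposited arrays of line 19.5 stood lower (75th percentile 6.79 to 6.80 on the log2 scale, against 6.93 to 6.97 in the other 6 arrays). The reason was not given in the sources used here. The shift depended on brightness: the median log2 change of line 19.5 was 0.0156 in the dimmest, -0.145 in the middle and -0.162 in the brightest of 3 equal parts of the genes. Counts are given as deposited and after median centring of every array, which raises dim genes of line 19.5 that had not shifted and so does not remove this dependence, with quantile normalization as an alternative. Array medians were 25.2 to 27.7 intensity units. Background signals and detection calls were not used here.

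The table holds 32321 probes. Genes were named through the platform annotation, which can be old: 19158 probes had exactly 1 gene symbol, 1388 several and 11775 were not listed and stay unnamed. Of the probes with 1 symbol, 19128 matched the RefSeq table (GRCh38.p14) by Entrez ID, 30 kept the annotation's symbol and 0 symbols needed updating. A gene with several probes (637 genes) was represented by the probe with the highest mean over all 9 arrays, which left 18404 genes, with no filter on low values. The files name no genome build, so no coordinates are printed, and the RefSeq table was used only for names, chromosomes and the order of neighbouring genes.

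Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in 1 model of all 9 arrays with a mean per group and no covariate, which leaves 6 residual degrees of freedom, with Benjamini-Hochberg adjustment over the 18404 genes and a threshold of 0.05. Contrasts were line 18.5 minus control, line 19.5 minus control and line 19.5 minus line 18.5; SE is the moderated standard error of a log2 difference. An exact test of 3 against 3 arrays cannot go below 0.1, so single genes rest on the spread that limma pools across genes. Gene lists (26, with 726 entries, 672 of them measured) were tested with camera at a preset correlation of 0.01, adjusted over the lists with at least 5 measured genes, with an estimated correlation and fry as alternatives. The lists were written from general knowledge: the PP6 holoenzyme, other PPP-family subunits, DNA replication, G2/M and mitosis, DNA damage repair, p53 targets, NF-kB, anti-inflammatory and interferon signalling, hepatocyte genes, acute phase and complement, cholesterol, fatty acid and drug metabolism, stress responses, splicing, mTOR, Hippo, Wnt, glycolysis, histones, and markers of stellate, endothelial, immune and bile duct cells. Counts adjusted over the list alone use the same fit with adjustment within the list. Brightness-matched percentiles came from 10000 random lists drawn within 50 ranks of each member's mean.

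The grouping, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the holoenzyme members, the 5 largest rises and 5 largest falls per comparison with control with no overlap of arrays, the 10 highest and 10 lowest genes changed in both lines by the smaller change, the 5 largest differences each way between the lines, and up to 4 passing members per list (2 where none passed), leaving out symbols of uncharacterised and small RNA genes and of olfactory receptors. Other list members, such as MCM5, CDC6, KIF20A, CXCL8, ICAM1, RELB, TNF, MBL2, CP, C4BPA, HPX, F2, NR0B2, SPP1, PROM1, C1R, C1S, IL13RA1, PPP4C, NFKBIA, APOA1, APOC3, CYP7A1 and ABCG2, were named after their values were seen, as was the study of single chromosomes. Alternatives were the replicate number as a block, an intensity trend, robust eBayes, array weights, median centring, quantile normalization, removal of the dimmest probes, the mean of a gene's probes, every probe, only the 2 groups compared, a fold of at least 1.5, and each array left out in turn. On simulated data with 200 changed genes among the 18404 of the line 18.5 comparison, in 5 runs, 75.6% of 1.5-fold changes, 97.7% of 2-fold changes and 99.7% of 3-fold changes were found, and 4.32% of calls were unchanged genes. The noise was drawn as normal and independent for each gene with limma's moderated spread, without shifts between arrays or correlation between genes. The share of unchanged genes follows largely from that model, and these rates may not hold for the deposited arrays. Windows held 40 neighbouring genes with a mean at or above the median of all genes, moved by 20 genes. Arrays of a group differed by an SD of 0.205 to 0.251 of the log2 difference and arrays of different groups by 0.252 to 0.366, and no array was a duplicate of another. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.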

Results

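Gene expression was measured on 9 Affymetrix arrays in HepG2 cells, a hepatocellular carcinoma line that keeps many of the secretory functions of hepatocytes. The cells had been transduced with lentiviral short hairpin RNAs and selected in puromycin. Lines 18.5 and 19.5 carried different hairpins against PPP6C, which encodes the catalytic subunit of protein phosphatase 6 (PP6), a serine/threonine phosphatase of the PPP family. The control carried a hairpin with no target. Each of the 3 groups had 3 arrays that the labels call biological replicates, cultured for 48 h before RNA extraction. Array medians lay between 25.2 and 27.7 intensity units, and the median SD between replicates was 0.107, 0.103 and 0.111 on the log2 scale in control, line 18.5 and line 19.5. The number of arrays limits the precision of every value, and each hairpin was represented by a single selected line. The 1st principal component, with 42.1% of the variance, separated line 19.5 from the other 6 arrays, and the next, with 15.5%, separated control from line 18.5. The median of all genes in line 19.5 stood at log2 -0.113 against control, and that in line 18.5 at -0.0122. Values for line 19.5 are therefore also given after median centring of every array. Background was not assessed, so where a gene's mean intensity in a compared group lay below the medians of that group's arrays, its log2 value describes signal and gives no transcript ratio or order; such genes are called dim below. Besides those named as dim where they appear, PPP2R2B, ANKRD44, TNF, ANXA1, COL3A1 and CLEC4F were dim in all groups compared.

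PPP6C was far lower in both knock-down lines. Its intensity was 1336, 1382 and 1394 in the control arrays, 265.6, 269.1 and 298.4 in line 18.5 and 297.2, 320.6 and 278.2 in line 19.5. The transcript stood at 20.2% of control in line 18.5 (log2 -2.30, SE 0.0762, adjusted p = 1.95e-06) and at 21.8% in line 19.5 (log2 -2.20, -2.11 after centring, SE 0.0762, adjusted p = 1.48e-06). It was the 2nd largest fall in line 18.5 and the largest in line 19.5 among the genes tested. The lines differed from each other in PPP6C by 0.10 (adjusted p = 0.346), within the error. The other 6 measured members of the holoenzyme list, which encode its regulatory and ankyrin repeat subunits, did not pass the test in either line. PPP6R3 was at 0.27 in line 18.5 (adjusted p = 0.0604) and -0.05 in line 19.5, and ANKRD44 at 0.31 and -0.23. With PPP6C alone passing, the list was not shifted as a group (camera adjusted p = 0.887 in line 18.5 and 0.145 in line 19.5; adjusted over the list alone, 2 rose and 1 fell in line 18.5 and 1 fell in line 19.5). Among 26 measured subunits of other PPP-family phosphatases, 1 fell in line 18.5 (PPP4C, -0.29), a call that ended in all 6 fits with an array left out (adjusted p up to 0.156). In line 19.5, 1 rose (PPP2R2B, a regulatory subunit of protein phosphatase 2A, 0.66, 0.76 centred) and 11 fell, of which 2 passed after centring (adjusted over the list alone, 0 rose and 1 fell, and 1 rose and 12 fell). PPP3CA, a catalytic subunit of calcineurin, was among them at -0.39 (-0.29 centred, adjusted p = 0.0327). That list was not shifted as a group (camera adjusted p = 0.812 and 0.477).

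**Figure D1:**
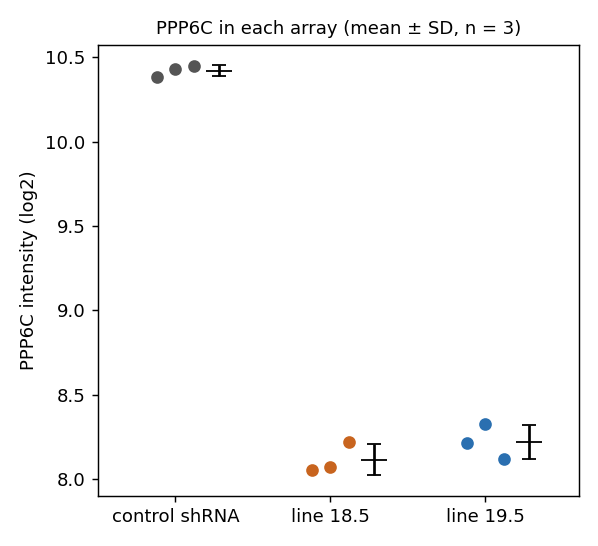
PPP6C intensity on the log2 scale (vertical axis, which does not start at 0) in each of the 3 control, 3 line 18.5 and 3 line 19.5 arrays; points are arrays and the bars beside them mean and SD. The control arrays lay between 1336 and 1394 intensity units and the 6 knock-down arrays between 265.6 and 320.6.

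The comparison of line 18.5 with control asked which transcripts differed from control in a culture with little PPP6C. PLG, which encodes the clot-dissolving zymogen plasminogen, rose 7.19-fold (log2 2.85, SE 0.116, adjusted p = 4.99e-06). IGFBP1, a liver-secreted binding protein for insulin-like growth factors, rose 4.39-fold (log2 2.13, SE 0.0972), and SLC19A3, a thiamine transporter, rose by log2 2.09 (SE 0.0774). H2BC12, a histone H2B gene, rose 5.55-fold and SESN3, a stress-response sestrin, by log2 2.29. SLC19A3 and SESN3 were dim in control. CES1, the main carboxylesterase of liver, was 5.56-fold lower (log2 -2.47, SE 0.112, adjusted p = 8.6e-06). DLK1, a fetal liver and progenitor marker, was 3.81-fold lower (log2 -1.93, SE 0.0692), and the glutathione transferase GSTA1 2.68-fold lower (log2 -1.42, SE 0.0737). CES1P1, a pseudogene copy of CES1, was at -2.00, and GSTA2, a close paralog of GSTA1, at -0.94. Sharing of signal between such copies was not tested. In all, 485 of 18404 genes passed limma at an adjusted p under 0.05, 263 higher and 222 lower than control. Leaving out any of the 6 arrays in turn moved the count by over 1.5 times, to 261, 243 and 312 without control replicates 1, 2 and 3 and to 278, 256 and 244 without line 18.5 replicates 1, 2 and 3. The count was 1247 with an intensity trend in eBayes, 913 without the dimmest probes, 317 with only these 2 groups, 277 with every probe and 185 with a fold of at least 1.5 as well.

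Genes on chromosome 11, as the RefSeq table (GRCh38.p14) places them, stood out in line 18.5. Of the 263 genes that rose, 64 (24.3%) lie there, against 6.69% of the genes tested, and 2 of its genes fell. SESN3, SERPING1, LYVE1, DDB2 and DHCR7 are among those that rose, and PPP6R3, at 0.27, lies there too. Over the 547 chromosome 11 genes in the brighter part of the array, the median change was 0.193 above that of other chromosomes, and 89.6% lay above it. The 3 line 18.5 arrays averaged 0.196 on this measure (SD 0.0085, n = 3), control 0.00193 (SD 0.0048, n = 3) and line 19.5 0.0192 (SD 0.0053, n = 3). Per array, each gene was taken relative to its control mean, so the small control value is set by construction. Camera over chromosomes gave an adjusted p of 4.96e-29, and adjusted p = 0.00176 with an estimated correlation. In line 19.5 its adjusted p was 0.946. Without chromosome 11, 406 genes were called in line 18.5. Chromosome 11 was tested after the shift had been seen.

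**Figure D2:**
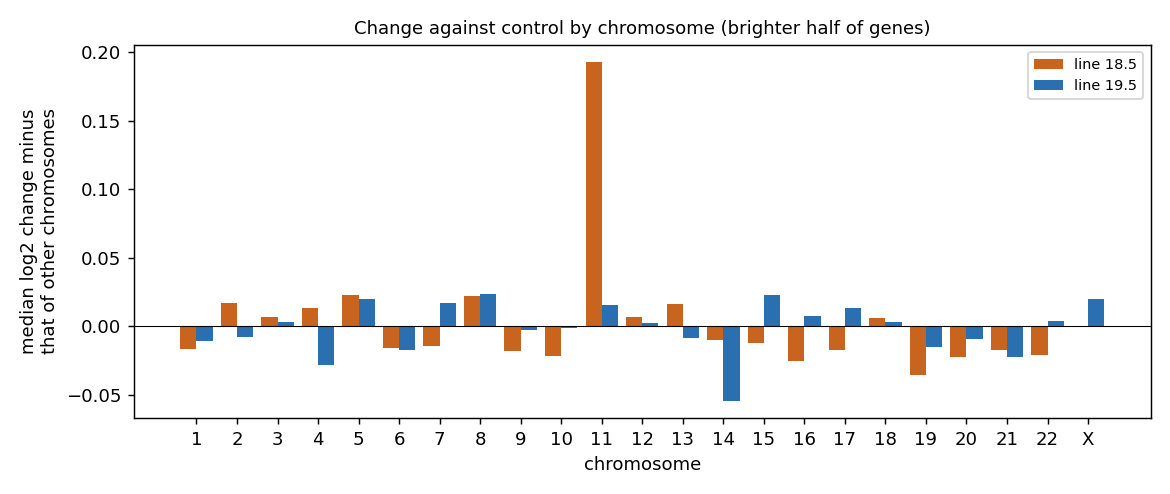
Median log2 change against control of the brighter genes of each chromosome (horizontal axis) minus that of the genes on all other chromosomes (vertical axis), for line 18.5 and line 19.5; each bar is 1 median, with no error bar. Chromosome 11 stood at 0.193 in line 18.5 and at 0.0153 in line 19.5.

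Genes of DNA replication were lower in line 18.5 as a group, and those of the acute phase and complement higher. Of 47 measured replication genes, 0 rose and 3 fell. These were MCM5 (-0.39) and MCM10 (-0.34), which serve the replicative helicase, and CDC6 (-0.37), which loads it (adjusted over the list alone, 0 rose and 5 fell, list median -0.155, camera adjusted p = 3.24e-09 and adjusted p = 0.0338 with an estimated correlation). FEN1, the flap endonuclease of lagging-strand synthesis, was at 0.03 and did not pass, and it lies on chromosome 11. Of 28 acute phase and complement genes, 5 rose and 2 fell (adjusted over the list alone, 13 rose and 3 fell, list median 0.237, camera adjusted p = 6.52e-06 and adjusted p = 0.0338 with an estimated correlation). The C1 inhibitor gene SERPING1 rose by 1.10 (SE 0.0952), the protease inhibitor SERPINA3 by 0.81 (SE 0.0616), the lectin MBL2 by 0.72, ceruloplasmin (CP) by 0.59 and C4BPA by 0.53. HAMP, the iron hormone hepcidin, fell (-0.78, SE 0.0901), as did the heme carrier HPX (-0.95). SERPING1 lies on chromosome 11. Of 41 genes of G2/M and mitosis, 0 rose and 2 fell. They were CDC20, which activates the anaphase-promoting complex (-0.39), and the kinesin KIF20A (-0.33; adjusted over the list alone, 0 rose and 2 fell, list median -0.147, camera adjusted p = 2.19e-06 and adjusted p = 0.136 with an estimated correlation). The calls of DNA replication, G2/M and acute phase lists passed in all 6 fits with an array left out. The single calls of MCM10 and CDC20 were weaker: that of MCM10 ended whichever of the 6 arrays was left out (adjusted p up to 0.158 without control replicate 2). That of CDC20 ended in 4 of these 6 fits (up to 0.121 without control replicate 2) and, like that of CDC6, after centring (CDC20 adjusted p = 0.0506; CDC6 0.0569). Those of MCM5, CDC6 and KIF20A ended in 5, 5 and 6 of them (up to 0.141, 0.158 and 0.116), and that of C4BPA in 1 (0.0516).

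A further 9 lists passed camera in line 18.5 with a preset correlation and none of these with an estimated correlation. Among 35 genes of NF-kB and inflammatory signalling, 5 rose and 1 fell (adjusted over the list alone, 7 and 2, camera adjusted p = 0.0175 and adjusted p = 0.234 with an estimated correlation). The chemokines CCL20 (0.84, SE 0.0695) and CXCL8 (0.54), the adhesion molecule ICAM1 (0.62), the NF-kB inhibitor TNFAIP3 (0.66) and the subunit RELB (0.45) rose, and TNF fell (-0.45). The calls of CXCL8, RELB and TNF ended in 3, 5 and 5 of 6 fits with an array left out (adjusted p up to 0.0624, 0.101 and 0.0881). Of 24 p53 target genes 3 rose, TP53INP1 (0.81), DDB2 (0.46) and PLK3 (0.39), and 0 fell (adjusted over the list alone, 3 and 0, camera adjusted p = 0.03 and adjusted p = 0.186 with an estimated correlation). DDB2, a damage recognition factor, lies on chromosome 11, and its call and that of PLK3 each ended in 5 of 6 fits with an array left out (adjusted p up to 0.0934 without line 18.5 replicate 3 and 0.0881 without line 18.5 replicate 2). Of 32 hepatocyte genes 4 rose and 1 fell (adjusted over the list alone, 7 and 4, camera adjusted p = 0.0418 and adjusted p = 0.278 with an estimated correlation). The fibrinogen chain gene FGB rose by 0.61, prothrombin (F2) by 0.36 and the nuclear receptor NR0B2 by 0.47. F2 lies on chromosome 11, and its call ended in 5 of 6 fits with an array left out (adjusted p up to 0.0963). Of 23 Wnt and liver progenitor genes 5 rose, among them SPP1 (0.73) and PROM1 (0.59), and DLK1 fell (adjusted over the list alone, 7 and 2, camera adjusted p = 0.0488 and adjusted p = 0.156 with an estimated correlation). Of 25 glycolysis and hypoxia genes 2 rose, NDRG1 (0.48) and PDK1 (0.33), and 0 fell (adjusted over the list alone, 4 and 0, camera adjusted p = 0.0175 and adjusted p = 0.136 with an estimated correlation). Of 27 interferon response genes 1 rose, XAF1 (0.43; adjusted over the list alone, 4 rose and 1 fell, camera adjusted p = 0.03 and adjusted p = 0.136 with an estimated correlation). Lower as a group was DNA damage repair (31 genes, 0 rose and 0 fell; adjusted over the list alone 0 and 7, camera adjusted p = 0.021 and adjusted p = 0.186 with an estimated correlation). So were pre-mRNA splicing (38 genes, 0 and 0; adjusted over the list alone 0 and 0, camera adjusted p = 0.021 and adjusted p = 0.136 with an estimated correlation), and heat shock and oxidative stress (17 genes, 0 rose and 1 fell, the small heat shock protein HSPB1 at -0.66; adjusted over the list alone 0 and 3, camera adjusted p = 0.0488 and adjusted p = 0.156 with an estimated correlation). Among random lists matched on brightness, the median of the DNA damage repair list lay at percentile 16.7, between the 5th and 95th percentiles. A difference of this list from genes of like brightness was thus not resolved. The other lists called lay at percentiles 0 (DNA replication), 0 (mitosis), 1.06 (splicing), 3.9 (heat shock), 96.7 (interferon), 97.7 (glycolysis), 98 (hepatocyte), 98 (Wnt), 99.4 (NF-kB), 100 (p53) and 100 (acute phase). The 12 lists became 3 without control replicate 3, 4 without line 18.5 replicate 3, 7 with camera on ranks and 2 with an estimated correlation. The calls of PDK1, XAF1 and the heat shock and Wnt lists were among those that ended under single changes of setting, PDK1 after centring (adjusted p = 0.0569) and XAF1 without control replicate 1 (0.122). With an array left out, the heat shock and Wnt lists passed camera in 1 of 6 fits, hepatocyte in 2 and interferon in 3. The p53, repair, splicing and glycolysis lists passed in 4 of 6 and NF-kB in 5.

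The comparison of line 19.5 with control asked the same of the other hairpin. SPINK1, a secreted trypsin inhibitor, rose from a mean of 12.18 intensity units in control, below the control array medians, to 682.7 (log2 5.81, 5.90 centred, SE 0.0953, adjusted p = 7.19e-09). SLC19A3 (log2 2.94, 3.03 centred, SE 0.0774), the membrane protein POPDC3 (2.17), the hyaluronan receptor LYVE1 (2.16) and the metalloprotease meprin subunit MEP1A (2.06) rose as well. SPINK1 and these 4 genes were dim in control, and MARK2P21 was dim in both groups. GSTA1 was 4.58-fold lower (log2 -2.20, -2.10 centred, SE 0.0737). NPNT, the matrix protein nephronectin, was 4.34-fold lower (log2 -2.12, -2.02 centred, SE 0.0943) and NR5A2, a nuclear receptor of bile acid and cholesterol metabolism, 3.56-fold lower (log2 -1.83, -1.74 centred, SE 0.0741). The pseudogene MARK2P21 was at -1.49 on its brighter probe and at 0.09 on its other probe, so that its probes disagreed. In all, 5078 genes passed, 1048 higher and 4030 lower (20.6% higher). After median centring 2985 passed, 1387 higher and 1598 lower (46.5% higher), and all 1048 rises and 1598 of the falls were called under both scalings. Centring raised every change of line 19.5 by the same amount, so this agreement follows largely from the scaling and is no separate support. The count was 2784 after quantile normalization, 873 with a fold of at least 1.5 as well and 3340 without control replicate 2.

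Replication genes were lower in line 19.5 too, and most of them passed singly. Of 47, 0 rose and 36 fell, 18 of these after centring (adjusted over the list alone, 39 fell, 30 after centring). The list median was -0.355, or -0.242 relative to the median of all genes (camera adjusted p = 8.83e-09 and adjusted p = 0.0407 with an estimated correlation). MCM10 was at -0.73 (-0.63 centred, SE 0.0724, adjusted p = 0.000526), the DNA ligase gene LIG1 at -0.60 (-0.51 centred), ORC1 of the origin recognition complex at -0.57 (-0.48 centred) and FEN1 at -0.57 (-0.47 centred). Of 41 genes of G2/M and mitosis, 0 rose and 19 fell, 2 of them after centring, CDCA8 (-0.40 centred) and the kinetochore gene NDC80 (-0.40 centred; adjusted over the list alone, 23 fell, 2 after centring, camera adjusted p = 0.00123 and adjusted p = 0.221 with an estimated correlation). Of 31 DNA damage repair genes 0 rose and 14 fell, 3 after centring, among them the single-strand break scaffold XRCC1 (-0.36 centred; adjusted over the list alone, 22 fell, 2 after centring, camera adjusted p = 0.00462 and adjusted p = 0.167 with an estimated correlation). Of 38 splicing genes 0 rose and 18 fell, after centring 1 and 6, with RBM39 at -0.43 (-0.34 centred; adjusted over the list alone, 1 rose and 21 fell, after centring 1 and 6, camera adjusted p = 0.00761, 0.0544 after centring and adjusted p = 0.149 with an estimated correlation). After quantile normalization the camera calls of the mitosis, repair and splicing lists ended (adjusted p = 0.163, 0.198 and 0.239).

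Acute phase and complement genes were higher in line 19.5. Of 28, 13 rose and 1 fell, after centring 15 and 0 (adjusted over the list alone, 16 and 3, after centring 18 and 1, list median 0.323, or 0.437 relative to all genes, camera adjusted p = 1.1e-09 and adjusted p = 0.0153 with an estimated correlation). SERPING1 rose 2.83-fold as deposited (log2 1.59 after centring, SE 0.0952), HAMP by 1.05 (1.14 centred, SE 0.0901), SERPINA3 by 1.03 (1.13 centred, SE 0.0616) and the complement proteases C1R and C1S by 0.85 and 0.79. SAA2, a serum amyloid gene, dim in both groups, was at 1.16 on 1 probe (adjusted p = 0.0201, 0.0612 without control replicate 2) and at 0.24 on the other, which did not pass. Of 30 anti-inflammatory genes 3 rose and 1 fell, after centring 5 and 1 (adjusted over the list alone 3 and 1, after centring 5 and 1). ANXA1 (1.01, 1.11 centred), TNFAIP3 (0.50, 0.59 centred) and IL13RA1 (0.24, up to adjusted p = 0.0813 with an array left out) rose and the glucocorticoid receptor gene NR3C1 fell (-0.43, -0.33 centred, camera adjusted p = 0.0434, 0.0544 after centring and adjusted p = 0.149 with an estimated correlation). In line 18.5, 2 of these 30 rose, TNFAIP3 and PPARG (0.62; adjusted over the list alone, 2 rose and 2 fell, camera adjusted p = 0.249). Among 12 endothelial markers 4 rose and 0 fell. These were LYVE1 (2.16, 2.25 centred), TIE1 (0.85, 0.95 centred), CDH5 (0.43, 0.52 centred) and ERG (0.32, 0.42 centred; adjusted over the list alone, 4 rose and 1 fell, after centring 4 and 0, camera adjusted p = 0.0252, 0.0544 after centring and adjusted p = 0.149 with an estimated correlation). In line 18.5 LYVE1 alone passed (adjusted over the list alone 1 and 0, camera adjusted p = 0.307). TIE1, CDH5 and ERG were dim in both groups and each lost their calls when some arrays were left out (adjusted p up to 0.0671 without line 19.5 replicate 2, 0.0665 without line 19.5 replicate 3 and 0.124 without control replicate 1). Among random lists matched on brightness, the endothelial median lay at percentile 86.6 and the splicing median at 6.73, both between the 5th and 95th percentiles. The others lay at 0 (DNA replication), 2.46 (DNA damage repair), 3.17 (mitosis), 99.9 (anti-inflammatory) and 100 (acute phase). The 7 lists called in line 19.5 became 4 after median centring, 4 after quantile normalization and 2 with an estimated correlation. With an array left out, the anti-inflammatory list passed camera in 3 of 6 fits (adjusted p up to 0.108).

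**Figure D3:**
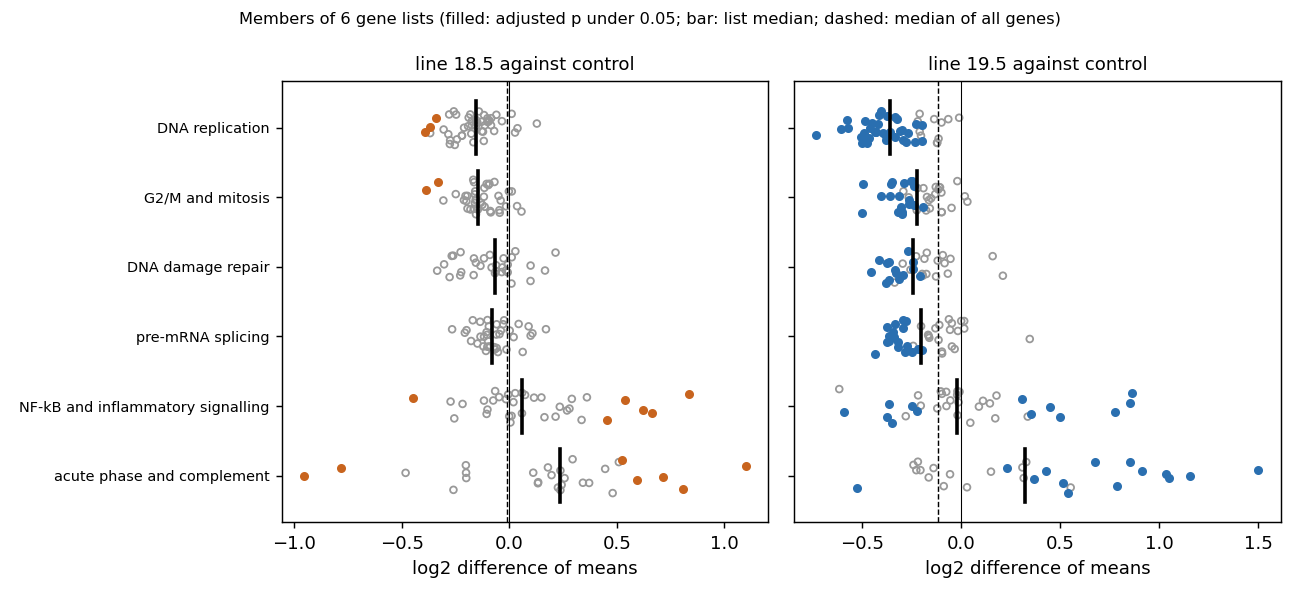
Log2 difference from control (horizontal axes) of the members of 6 gene lists (vertical axis) in line 18.5 and line 19.5; each point is 1 gene, filled where it passed the test, short bars are list medians and the dashed line is the median of all genes. The DNA replication medians were -0.155 and -0.355 and those of the acute phase and complement list 0.237 and 0.323.

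Markers of other liver cell types were not shifted as groups in line 18.5, nor were the stellate, immune and bile duct lists in line 19.5. Of 13 stellate cell and fibroblast markers, 0 passed in line 18.5, where 0 also passed with the list alone, and in line 19.5 1 rose and 3 fell, after centring 1 and 1 (adjusted over the list alone 1 and 3, camera adjusted p = 0.812 and 0.736). The fibrillar collagen gene COL3A1 was at -0.37 in line 19.5 (-0.28 centred). Of 15 immune and Kupffer cell markers, 0 passed in line 18.5 and 1 fell in line 19.5, CLEC4F at -0.49 (adjusted over the list alone 0 and 1, camera adjusted p = 0.765 and 0.678). Of 11 bile duct markers ANXA4 fell in both lines (-0.51 and -0.76) and KRT19 rose in line 19.5 (0.74, 0.83 centred; adjusted over the list alone 0 rose and 1 fell, and 1 rose and 1 fell, camera adjusted p = 0.9 and 0.458).

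Changes common to both lines were examined because the hairpins share their target. SLC19A3, IGFBP1 and PLG were among the genes that rose in both. Another was UGT2B4, a bile acid glucuronosyltransferase (1.49, SE 0.0761, in line 18.5 and 1.66, 1.75 centred, in line 19.5). Others were the sulfate donor synthase PAPSS2 (1.61 and 1.48), the secreted Wnt antagonist FRZB (1.43 and 2.00), the pantetheinase VNN1 (1.14 and 2.01), SERPING1, TMC7 (1.26 and 1.09) and LYVE1 (1.07 and 2.16). SLC19A3, PAPSS2, FRZB, VNN1 and LYVE1 were dim in control, and of the genes below, OXCT1 and HOXC9 were dim in both lines and CES1P1 in line 18.5. Lower in both were PPP6C, GSTA1, NPNT, CES1P1 and the ketone-using enzyme OXCT1 (-1.21 and -1.15). So were HOXC9 (-1.11 and -1.24), the ethanolamine kinase ETNK2 (2-fold and 2.07-fold lower), the betaine transporter SLC6A12 (-0.97 and -0.91), EML6 (-1.04 and -0.89) and the actin-bundling protein FSCN1 (-1.16 and -0.86). The call of LYVE1 in line 18.5 ended in 3 of 6 fits with an array left out (adjusted p up to 0.0667 without line 18.5 replicate 2). In all, 254 genes passed in both lines in the same direction, 116 higher and 138 lower (45.7% higher). After centring 201 did, 118 higher and 83 lower (58.7% higher). Independent lists of these sizes would share 15 and 48.6 genes, and after centring 16.4 and 15.1. Opposite calls numbered 26 and 7 against 57.6 and 12.6, and after centring 17 and 7 against 18.8 and 13.1. Both comparisons used the same 3 controls. In 100 simulations of unchanged groups, all arrays were drawn as random noise, controls included, and the simulated controls served both comparisons. The simulated comparisons shared 0 calls. Unchanged groups give almost no calls, so this sets no level for the overlap of called lists. The simulated values that follow also do not carry the deviations of the actual control arrays. Across genes, which are not independent replicates, the fold changes correlated at 0.358 against a simulated 0.499 with no effect, and their covariance was 0.0208 against 0.0076, a difference of 0.0132. After centring 61.7% of genes had the same sign in both lines, against a simulated 66.7%. The 3 controls could not be split into parts with at least 2 arrays each, so part of the excess may come from the shared controls. The count was 652 with an intensity trend, 476 without the dimmest probes, 169 with only the 2 groups of each comparison, 155 with every probe, 78 with a fold of at least 1.5, 150 and 145 without control replicates 1 and 2, and 169, 151 and 149 without line 18.5 replicates 1, 2 and 3.

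**Figure D4:**
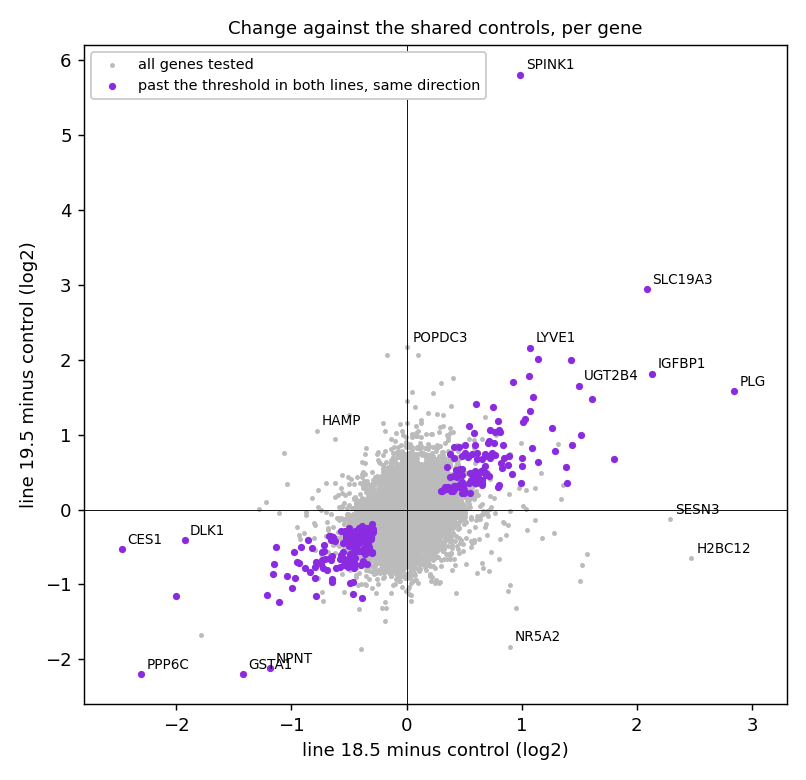
Log2 difference from control of each gene in line 18.5 (horizontal axis) and line 19.5 (vertical axis), with the same 3 control arrays in both; each point is 1 gene and coloured points are the 254 genes that passed in both lines in the same direction. SPINK1 stood at 0.99 and 5.81, and SESN3 at 2.29 and -0.13.

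The lines also differed from each other. SPINK1 was higher in line 19.5 than in line 18.5 (log2 4.82, SE 0.0953, adjusted p = 3.87e-08), as were MEP1A (2.23), POPDC3 (2.16), TEX15 (1.96) and CES1 (1.94). SPINK1, MEP1A, POPDC3 and TEX15 were dim in line 18.5, and of the genes below, PCDHB5, SESN3 and ARFGEF3 were dim in line 19.5. H2BC12 was 8.69-fold lower in line 19.5 (log2 -3.12, SE 0.142), as were NR5A2 (-2.73), the protocadherin PCDHB5 (-2.47), SESN3 (-2.42) and ARFGEF3 (-2.27). H2BC12 and NR5A2 were above control in line 18.5 and below it in line 19.5, with both changes past the threshold. The signals of PCDHB5 and ARFGEF3 did the same, but as these genes were dim in line 19.5 their values there give no transcript order. The call of H2BC12 in line 19.5 ended after quantile normalization (adjusted p = 0.052) and those of PCDHB5 without single arrays (up to 0.0686 without line 18.5 replicate 2 and 0.0773 without line 19.5 replicate 3). HAMP went the other way, -0.78 in line 18.5 and 1.05 in line 19.5 (difference 1.83, SE 0.0901). In all 4390 genes differed between the lines, 986 higher and 3404 lower in line 19.5 (22.5% higher). After centring 2907 did, 1497 higher and 1410 lower (51.5% higher), with all 986 and 1410 of these called under both scalings. Here too centring raised each difference by the same amount, so the agreement follows largely from the scaling. The acute phase and complement list was higher in line 19.5 than in line 18.5 (camera adjusted p = 0.00247 and adjusted p = 0.208 with an estimated correlation), and the replication list did not pass for this difference (camera adjusted p = 0.059). The count was 870 with a fold of at least 1.5 as well and 2908 without line 18.5 replicate 2.

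Genes of drug and bile acid metabolism moved in both directions. Of 36 measured, 6 rose and 2 fell in line 18.5 and 5 rose and 9 fell in line 19.5, after centring 5 and 5 (adjusted over the list alone, 9 and 4, and 5 and 9, camera adjusted p = 0.0835 and 0.249). CYP7A1, the rate-limiting enzyme of bile acid synthesis, rose by 0.59 (a call that ended in 4 of 6 fits with an array left out, adjusted p up to 0.0649) and 0.86, the efflux transporter ABCG2 by 0.71 and 0.88, and the alcohol dehydrogenase ADH4 by 1.05 in line 19.5 (1.14 centred). Of 28 genes of fatty acid and triglyceride metabolism, 2 rose and 2 fell in line 18.5 and 1 rose and 9 fell in line 19.5, after centring 1 and 5 (adjusted over the list alone, 6 and 7, and 1 and 9, camera adjusted p = 0.794 and 0.736). The triglyceride synthase DGAT1 (-0.92, SE 0.0655, and -0.50, -0.40 centred) and the fatty acid receptor CD36 (-0.69 and -0.81, -0.71 centred) fell in both lines. CD36 was dim in all groups and lost its call in line 18.5 in 2 of 6 fits with an array left out (adjusted p up to 0.0676 without line 18.5 replicate 2). Of 19 cholesterol synthesis genes, DHCR7 rose in line 18.5 (0.31), where it lies on chromosome 11 and lost its call after centring and in all 6 fits with an array left out (adjusted p up to 0.132 without control replicate 2). In line 19.5, 1 rose and 3 fell, after centring 1 and 0 (adjusted over the list alone, 2 and 0, and 1 and 3, camera adjusted p = 0.869 and 0.729). Of 27 genes of the unfolded protein and amino acid stress response, 0 passed in line 18.5 and 3 rose and 2 fell in line 19.5, after centring 4 and 0, with the cystine transporter SLC7A11 at 0.49 (adjusted over the list alone, 2 and 0, and 3 and 1, camera adjusted p = 0.9 and 0.235). Of 27 mTOR and insulin signalling genes, IGFBP1 passed in line 18.5, and in line 19.5 2 rose and 8 fell, after centring 2 and 1 (adjusted over the list alone, 1 and 0, and 2 and 8, camera adjusted p = 0.9 and 0.419). IGF1R, the receptor of insulin-like growth factors, was at -0.44 on its brighter probe and 0.11 on its other.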

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

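The tests of the overall level and of a brightness-dependent offset in line 19.5, and the comparison of the replication list with the mitosis list, were chosen after the results were seen. The other tests of this part were written before the results. The lines shared their target, yet 4390 genes were called between them (2907 after median centring), which drew attention to these genes. The line 19.5 arrays also stood lower in level, and each hairpin had 1 culture. The calls therefore do not establish a different response to the hairpins. Among named genes whose difference passed both as deposited and after median centring (limma, adjusted), these were higher in line 19.5 than in line 18.5, as log2 differences: SPINK1 4.82, MEP1A 2.23, POPDC3 2.16, TEX15 1.96, CES1 1.94, HAMP 1.83, DLK1 1.52. So were SAA2 1.36, ADH4 1.24, LYVE1 1.09, THBS1 1.03, VNN1 0.87, SLC19A3 0.85, ANXA1 0.84, CES1P1 0.84, TIE1 0.82. So were KRT23 0.80, KRT19 0.76, PPP2R2B 0.60, FRZB 0.57, AXL 0.54, PPP1R15A 0.51, IRS1 0.42, DGAT1 0.42. So were CSF1 0.42, SERPING1 0.40, SOX4 0.36, FSCN1 0.30, EBP 0.26, HSPB1 0.26, SERPINA3 0.22, TTR 0.22. These were lower in line 19.5: H2BC12 -3.12, NR5A2 -2.73, PCDHB5 -2.47, SESN3 -2.42, ARFGEF3 -2.27, LEF1 -1.46, SNAI2 -1.37, MARK2P21 -1.30, PLG -1.27. Lower there too were H3C8 -1.005, NPNT -0.93, VTN -0.81, GSTA1 -0.78, FEN1 -0.59, PDK1 -0.58, DDB2 -0.57, NDRG1 -0.54, ANKRD44 -0.54. The rest were TP53INP1 -0.48, IFI44L -0.47, RBM39 -0.45, LIG1 -0.45, PPARG -0.42, USP18 -0.41, MCM10 -0.39, DHCR7 -0.38, COL3A1 -0.37, IGF1R -0.35, PPP6R3 -0.32. Where a gene was dim in a line, the difference describes signal and gives no transcript ratio. In line 18.5 this held for SPINK1, MEP1A, POPDC3, TEX15 and CES1P1, among others. In line 19.5 it held for PCDHB5, SESN3, ARFGEF3, LEF1, SNAI2, MARK2P21, H3C8, SAA2 and TIE1, among others. PPP2R2B, ANKRD44, ANXA1 and COL3A1 were dim in both lines. SAA2, MARK2P21 and IGF1R are given on their brighter probe. Their other probes did not pass against control in either line (SAA2 -0.28 in line 18.5 and 0.24 in line 19.5, MARK2P21 0.0063 and 0.089, IGF1R 0.069 and 0.11). The acute phase and complement list also differed between the lines (camera adjusted p = 0.00247; adjusted p = 0.208 with an estimated correlation).

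Signals appeared in probes outside the comparisons above. Among probes with several gene symbols, 14 passed in line 18.5 and 227 in line 19.5. Among probes that the annotation does not list, 19 and 931 did. None of them is named here.

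Other splits of the arrays were counted for each result. For line 18.5 against control, 1 of the 10 splits of the 6 arrays, the real one, gave as many as 485 genes and the highest of the others gave 0. For line 19.5 against control the real split (1 of 10) gave 5078 and the highest other 0. For line 19.5 against line 18.5 it gave 4390 (1 of 10) and the highest other 0. For the lists, the real split (1 of 10) gave 12 in line 18.5 and the highest other 2, and in line 19.5 it gave 7 (1 of 10) and the highest other 3. With 10 splits no share under 0.05 can be reached. For genes called in both lines in the same direction, 1 of 100 splits of the 9 arrays, the real one, gave as many as 254. The highest other gave 28. Splits that mix the 3 groups widen the spread within groups and so lower the calls. They also do not address the shared controls or the 1 culture per hairpin, so no conclusion on chance is drawn for that count.

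More genes were called in line 19.5 (5078) than in line 18.5 (485). A lower overall level of the line 19.5 arrays did not account for this as the whole cause, since 2985 genes passed after median centring, against 391 in line 18.5. An offset that depends on brightness did not either, since 2784 passed after quantile normalization, against 494. The excess of falls over rises in line 19.5 did depend on the level, with 20.6% higher as deposited and 46.5% after centring. Line 19.5 arrays shared 0 identical gene values with any array of the other groups. Control arrays shared 9 to 27 with line 18.5 arrays, and line 19.5 arrays 12 to 22 among themselves. The 75th percentile of the line 19.5 arrays was 6.79 to 6.80 on the log2 scale, against 6.93 to 6.97 in the other 6. Together these values argue against a joint quantile normalization of all 9 arrays, which would remove such a difference in level. The sources did not state how the arrays were grouped for processing. How many of the line 19.5 calls come from separate processing, and how many from a difference of the line, the design cannot tell. A stronger response of this line to its hairpin, another target of that hairpin and changes fixed by chance when the culture was selected stay open too. The design has 1 line per hairpin and none of these was tested.

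For the DNA replication list, lower in both lines, an offset of genes of the same brightness was excluded, as its median lay at percentile 0 of 10000 random lists matched on brightness in line 18.5 and at percentile 0 in line 19.5. If a smaller share of dividing cells were the cause, the mitosis list could be lowered alike. The replication list lay at -0.0181 relative to the mitosis list in line 18.5 (SD 0.033, n = 3 arrays), where such a cause is a candidate explanation. It lay at -0.119 in line 19.5 (SD 0.036, n = 3 arrays), which did not clear the bound set for excluding it. No cell counts or cell cycle measurements were used here, so slower growth and a direct effect on replication genes stay open in both lines.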

How the results depend on the processing

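Alternatives without chromosomes 11 and 14, and median centring for the gene lists, were chosen after the data had been seen. The others were planned, and none of the planned ones was left out. PPP6C stayed past the threshold under every alternative run, with log2 values from -2.36 to -2.27 in line 18.5 and from -2.25 to -2.15 in line 19.5 over the fits with an array left out. The counts below moved by over 1.5 times, except that the ranges with an array left out also hold smaller moves. Genes in line 18.5 (485): 1247 with an intensity trend in eBayes, 913 without the dimmest probes, 277 with every probe, 317 with only the 2 groups, 185 with a fold of at least 1.5, and 243 to 312 with an array left out. Genes in line 19.5 (5078): 2985 with median centring, 2784 with quantile normalization, 873 with the fold, and 3340 to 3879 with an array left out (3340 without control replicate 2). Genes between the lines (4390): 2907 with centring, 870 with the fold, and 2908 to 3194 with an array left out (2908 without line 18.5 replicate 2). Genes in both lines (254): 652 with the trend, 476 without the dimmest probes, 155 with every probe, 169 with 2 groups, 78 with the fold, and 145 to 200 with an array left out. Lists in line 18.5 (12): 2 with an estimated correlation, 7 on ranks, 23 with fry in either direction, and 3 to 10 with an array left out (3 without control replicate 3, 4 without line 18.5 replicate 3). Lists in line 19.5 (7): 4 with quantile normalization, 4 with median centring, 2 with an estimated correlation, 18 with fry in 1 direction, 26 with fry in either direction, and 6 to 8 with an array left out. Fry tests whether a list's genes move and does not set them against other genes. A fold threshold can only lower a count. With an array left out every gene count fell, while the line 19.5 list count rose to 8 in some of those fits. For changes other than fry and the fold threshold the cause was not tested. In line 19.5 these lists passed fry as lower, while their camera direction was up without passing: Hippo and epithelial-mesenchymal genes (fry adjusted p = 0.0301), stellate cell markers (0.0447) and immune and Kupffer cell markers (0.0447).

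Without chromosome 11 line 18.5 kept a count of 406, without chromosome 14 line 19.5 gave 4852, and without both chromosomes 226 genes passed in both lines and 13 and 5 lists in the 2 comparisons. For named genes, 4370 values stayed on their side of the threshold, 44 passed newly, 404 no longer passed and 1 reversed, APOA1 in line 19.5 with the mean of its probes (log2 0.14). For lists these were 697, 53, 75 and 3. Deviations of arrays with the same replicate number correlated weakly (0.0093 to 0.052, each under 0.1), and 8 of 9 arrays correlated best with their own number, a hint from the data that the labels do not state. With the replicate block 312 genes were called in line 18.5, and the other counts moved by less than 1.5 times.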

Other observations

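The tests by chromosome and by stretch of neighbouring genes were prompted by the data. Those on brightness and on a few strong genes for chromosome 11 had their outcomes written before the result. Those on extra copies and on chromosome 14 were chosen after it was seen. Replication-dependent and linker histone genes went both ways. Of 22 measured, 1 rose and 3 fell in line 18.5 and 2 rose and 9 fell in line 19.5, after centring 2 and 5 (adjusted over the list alone, 2 and 4, and 2 and 11, camera adjusted p = 0.487 and 0.235). H2BC12 rose in line 18.5 (2.47) and fell in line 19.5 (-0.65), whereas the linker histone gene H1-5 fell in both (-0.98 and -0.56, -0.47 centred), losing its call in line 19.5 without control replicate 1 (adjusted p = 0.0554) and after quantile normalization (0.0741). Of 31 genes of Hippo, TGF-beta and epithelial-mesenchymal change, 1 rose and 1 fell in line 18.5 and 5 rose and 10 fell in line 19.5, after centring 5 and 3 (adjusted over the list alone, 2 and 3, and 5 and 10, camera adjusted p = 0.642 and 0.977). THBS1, the matrix protein thrombospondin, fell in line 18.5 (-0.77, SE 0.063) and stood above control in line 19.5 (0.26, 0.35 centred, adjusted p = 0.0509 without line 19.5 replicate 1), a difference of 1.03 (adjusted p = 5.85e-05), and the receptor kinase AXL rose in line 19.5 (0.63, 0.73 centred).

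Several lists called in line 18.5 did not pass camera in line 19.5. The difference between the lines did not pass for any of them (camera adjusted p from 0.0582 for glycolysis to 0.998 for NF-kB). In line 19.5, 7 NF-kB genes rose and 6 fell, after centring 8 and 2 (adjusted over the list alone 8 and 7, camera adjusted p = 0.0579). CCL20 stood at 0.86 (0.96 centred), CXCL2, dim in both groups, at 0.85, CSF1 at 0.78 and the inhibitor NFKBIA at -0.59. Hepatocyte genes moved apart, 3 up and 10 down, after centring 4 and 4 (adjusted over the list alone 3 and 10, camera adjusted p = 0.775). FGB (0.67, 0.77 centred) and the transthyretin gene TTR (0.57, 0.66 centred) rose, and the apolipoprotein gene APOC3 (-0.50) and the matrix ligand VTN (-0.50, -0.41 centred) fell. APOA1 was at -0.48 on its brightest probe and at 0.14 as the mean of its probes, which disagreed. Of the p53 targets 3 rose and 5 fell, after centring 3 and 0 (adjusted over the list alone 3 and 5, camera adjusted p = 0.478). Of interferon genes 4 rose and 3 fell, after centring 4 and 2 (adjusted over the list alone 4 and 3, camera 0.165). Of heat shock genes 0 rose and 5 fell, after centring 0 and 2 (adjusted over the list alone 0 and 5, camera 0.728). Of Wnt and progenitor genes 3 rose and 5 fell, after centring 3 and 3 (adjusted over the list alone 3 and 5, camera 0.495). Of glycolysis genes 1 rose and 4 fell, after centring 1 and 1 (adjusted over the list alone 1 and 4, camera 0.478). The keratin gene KRT23 (1.11, 1.21 centred) and the transcription factor gene SOX4 (0.87, 0.96 centred) were the largest rises of the progenitor list in line 19.5. A list's median, mean and camera direction differed in sign in line 18.5 for the stress response, mTOR, histone and immune lists. In line 19.5, where the median of all genes lay below 0, they differed for the p53, NF-kB, interferon, drug metabolism, stress response, Hippo, Wnt, stellate, immune and bile duct lists, whose medians lay below 0 and whose camera direction was up without passing.

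For chromosome 11, raised along its length in line 18.5, an offset of genes of the same brightness was excluded (percentile 100 of random sets matched on brightness), as were a few strongly raised genes (89.6% of its 547 brighter genes lay above the median of other chromosomes). All of its windows of 40 neighbouring genes (100%, 27 of 27) stood over 0.1 in line 18.5, from 0.118 to 0.267, against 1 of 422 windows elsewhere, but 1 of 27 also did in line 19.5 and no DNA was measured, so extra copies of chromosome 11 and a shared change of transcription cannot be told apart. For chromosome 14, the windows under -0.1 in line 19.5 were joined into a stretch of 100 brighter genes from TTC5 to SAV1. It lay at log2 -0.185 relative to other chromosomes in that line, while the other 197 genes stood at 0.0312. Per-array means were -0.165 (SD 0.0086, n = 3) in line 19.5 and -0.00306 in control (SD 0.01, n = 3), where the small value is set by construction. Of the stretch, 72 genes were called lower, 45 after centring, against 4030 and 1598 of all 18404 genes. The stretch holds brighter genes only, while the 18404 include dim genes, which fell less in line 19.5. Its median change was 0.0156 in the dimmest and -0.162 in the brightest of 3 equal parts of the genes. The shares are thus not like for like. These values come from the data that chose the stretch and are no separate test of it. The lowest window there, -0.242, lay below the lowest window anywhere in 1000 shuffles among genes of like brightness (-0.165), which excluded such an offset, and of 6 windows under -0.1 in that line 4 lay on chromosome 14 and 2 on chromosome 6, at -0.136 from H4C2 to ZSCAN26, a window also at -0.12 in line 18.5, and at -0.107 from BTN3A1 to TUBB. Camera did not call chromosome 14 as a whole (adjusted p = 0.946), and the biological explanation, a loss or silencing of this stretch in the culture, was not tested.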
